A study of Arabidopsis thaliana with 8 samples.

How the data were processed

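Arabidopsis roots and shoots were profiled on 8 Affymetrix arrays, 2 for each of control roots, roots grown on 40 µM selenate, control shoots and shoots grown on selenate. The deposited values are array signals, an intensity on a linear scale computed with MAS5 per the submitters' processing notes; the version of that software is not given in the sources used here. The deposited table shows that each array was scaled so that its mean signal without the highest and lowest 2% of probe sets is 500.04. MAS5 subtracts mismatch signals probe by probe and summarises each array alone, so low signals carry large relative errors, and its scaling assumes that total signal is alike in roots and shoots. Detection calls were not used here. Samples were assigned to groups by their titles.

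The table held 22810 probe sets, of which 64 controls were left out of the tests. Log2 values were taken after adding a pseudocount of 25.0, which is 5% of the scaled mean, so fold changes understate those of weakly expressed genes. Probe sets were tested if their signal reached 100, which is 20% of the scaled mean, on at least 2 of the 8 arrays, which left 16049. Models were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group, a variance trend on mean signal, 4 residual degrees of freedom and an estimated 5.12 prior degrees of freedom. The spread was shared by the 4 groups, although shoot replicates differed more than root replicates. P-values were adjusted by the Benjamini-Hochberg method over all probe sets tested, and a call is an adjusted p under 0.05. The contrasts were selenate against control in roots and in shoots, the difference between these responses, and control shoots against control roots.

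Gene names came from a table of the platform's annotation, updated by gene identifier from the RefSeq annotation of assembly TAIR10.1. That table gives 1 gene for 13513 probe sets, several for 503 and none for 8730, and 13436 of the single-gene probe sets were found in RefSeq. A probe set without a listed gene is unnamed here, which says nothing about whether it has a gene. The build behind the probe sets is not given in the sources used here, so no coordinates are printed. Probe sets whose names end in _s_at or _x_at can bind transcripts of several genes, and their values are uncertain.

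Before the data were examined, 24 gene lists with 509 entries by locus were fixed, together with the tests and most of the other settings. Only 70 of the entries were on the probe table and 59 were tested, in 21 lists; no sulfate transporter, nitrogen assimilation or phosphate starvation gene could be named, and these 3 lists gave no result. Where a gene had several probe sets, the one with the highest mean signal stood for it. Lists with at least 3 tested genes, 10 in number, were tested against 8638 genes with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. The adjustment ran over these 10 lists, and not over all 24 as first planned, since the others had too few genes. None of the camera calls in the selenate comparisons or their difference held with an estimated correlation.

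The genes named per organ were fixed by a rule: the 10 largest rises and 10 largest falls among called probe sets that match 1 gene with a symbol other than its locus code and have both selenate arrays beyond both control arrays. Up to 4 members of each list that were called over all probe sets, or else over the list alone, and every tested sulfate assimilation gene were named as well. For the difference between organs and for the control organs the 5 largest each way were named. PSAN, PRK, GSTU28, EXPA18, LTI30 and PYK10 fall outside this rule in the selenate comparisons and were chosen after their values were seen, as were EXPA7, EXPA18 and PYK10 in the control organs, AT1G04770 for the difference, and the members of added lists in the closing section.

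The procedure was tested on simulated data with 200 of 16049 probe sets changed. With the spread of each organ, the root comparison recovered 90% of the 2-fold and 100% of the 4-fold changes, and the shoot comparison 83% and 100%. False calls made up 1.55% of the calls in the root comparison and 20.8% in the shoot comparison; with equal spreads in both organs they made up 3.54% and 3.55%. In each comparison the set test recovered all 3 shifted lists of 10 and called 0 others, with limma's camera. The simulated genes varied independently, and all members of a shifted list rose by the same amount. The simulation therefore says nothing about lists whose genes vary together. Within an organ, simulated probe sets of like mean signal were given the same spread, and deviations shared between arrays were not simulated. The percentages recovered and falsely called may therefore not hold for the deposited data.

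The other settings fixed beforehand were a pseudocount of 1% of the scaled mean or 4 times as large, no filter or a stricter one, quantile normalization over all arrays or within organ, median centring, no variance trend, a robust variance, the arrays of 1 organ alone, the replicate number as a block within or across organs, a minimum change of 2-fold, each array left out in turn, and an estimated correlation. Added after seeing the data were the 3'/5' ratio of GAPDH as a covariate, a weight for each organ, leaving out the 2 shoot arrays with high ratios, and a crossed pairing of the shoot arrays. Without these 2 arrays each shoot group kept 1 array, so the fit had no measure of the spread in shoots. RNA integrity ratios used the GAPDH, actin and ubiquitin control probe sets of the array.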

Results

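Transcript levels were measured on 8 Affymetrix oligonucleotide arrays of Arabidopsis thaliana, ecotype Ws (Wassilewskija). The plants were 10 days old and had grown vertically on half-strength Murashige and Skoog medium, either without added selenate or with 40 µM selenate, a selenium oxyanion that resembles sulfate. Roots and shoots were separated, which gave 4 groups of 2 arrays: control roots, selenate roots, control shoots and selenate shoots. The labels do not say that the 2 arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Replicate arrays correlated across probe sets at r = 0.987 in control roots, 0.986 in selenate roots, 0.962 in control shoots and 0.976 in selenate shoots. The standard deviation of the difference between replicates was 0.26 and 0.28 (log2) in control and selenate roots, against 0.51 and 0.41 in control and selenate shoots. The number of probe sets with a signal of at least 100 was between 13223 and 14622 per array, and the small number of arrays limits the precision of every value below. RNA integrity, read from the ratio of 3' to 5' signals of the GAPDH control probe sets, was between 0.783 and 0.868 on the root arrays. On the shoot arrays this ratio was 2.03 for control 1, 10.4 for control 2, 7.34 for selenate 1 and 2.95 for selenate 2, so that the 2 highest ratios fell on 1 array of each shoot group. The ratio of the ubiquitin control probe sets was between 2.12 and 2.75 on the root arrays, 4.38 and 4.88 on the control shoots and 5.24 and 6.11 on the selenate shoots, so by this measure it was higher on both selenate shoot arrays. The actin ratio was between 4.74 and 9.07 on the root arrays and between 21.2 and 55.9 on the shoot arrays. All 3 ratios were higher on every shoot array than on any root array. RNA integrity and organ therefore cannot be told apart between control shoots and control roots.

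**Figure D1:**
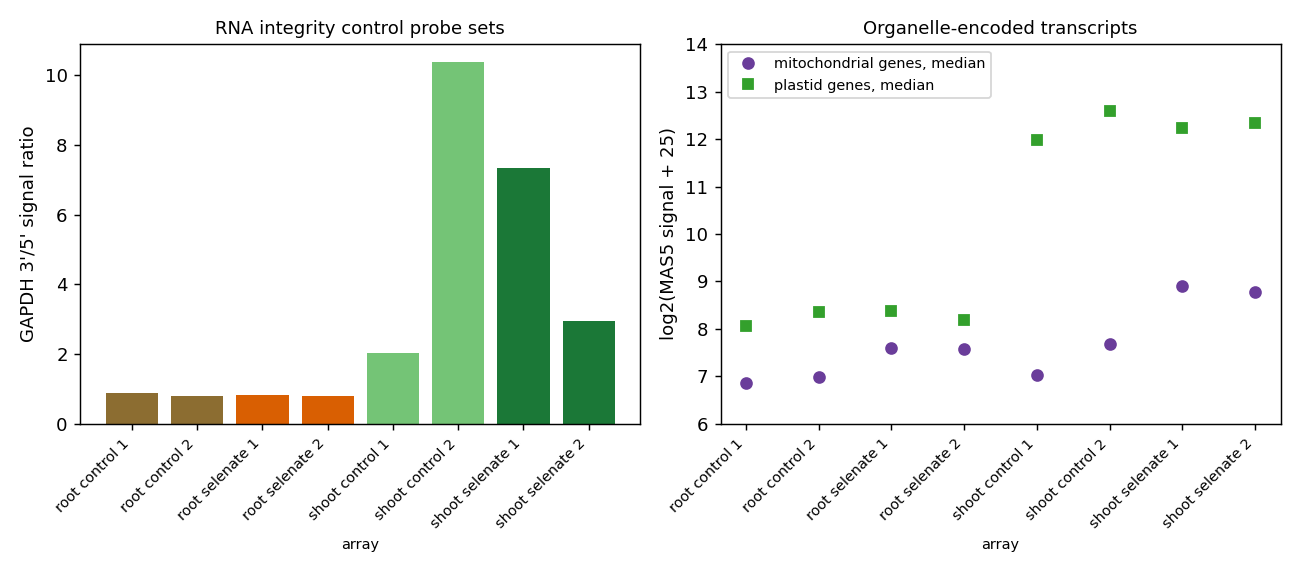
Left, GAPDH 3'/5' signal ratio on each array, bars from 0; right, median log2(signal + pseudocount) of mitochondrially and plastid-encoded genes on each array. The ratio was highest at 10.4 on control shoot 2 and 7.34 on selenate shoot 1, and the 2 selenate shoot arrays had mitochondrial medians of 8.89 and 8.77, against 7.02 and 7.67 for the control shoots.

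Green-tissue transcripts marked the organs in the comparison of control shoots with control roots. All 7 tested members of the photosynthesis list were higher in shoots, with a mean log2 difference of 5.54 (limma camera, adjusted p = 8.37e-07; adjusted p = 0.0525 with an estimated correlation). SBPASE, an enzyme of the Calvin cycle, had a signal of 24415 ± 8542 (SD, n = 2) in shoots and 162 ± 27.2 in roots, a 128-fold difference. CaS, PRK, HPR and LHCB4.2 were 120-fold, 112-fold, 99.4-fold and 98.3-fold higher in shoots. In the other direction OSM34 (osmotin), PDF2.5 (a defensin), GSTU25 (a glutathione transferase), SBT4.12 (a subtilase) and HRGP1 (a hydroxyproline-rich cell wall protein) were 81.3-fold, 69.6-fold, 68.7-fold, 59.3-fold and 49.7-fold higher in roots. Among all called probe sets, named or not, the largest differences were 265-fold higher and 293-fold lower in shoots. Both tested root hair genes, EXPA7 and EXPA18, and the root marker PYK10 were lower in shoots, with log2 differences of -3.81, -3.82 and -1.24, and that of EXPA18 was -4.61 without shoot control 1 and -3.03 without shoot control 2 or both shoot arrays with high ratios. With 4 times the pseudocount the log2 differences were 6.14 for CaS, -5.28 for OSM34, -4.37 for PDF2.5, -4.80 for GSTU25, -4.67 for SBT4.12, -4.96 for HRGP1, -2.41 for EXPA7 and -2.58 for EXPA18. With a pseudocount of 1% of the scaled mean they were -7.68 for PDF2.5, -6.85 for GSTU25, -6.55 for SBT4.12, -4.89 for EXPA7 and -4.86 for EXPA18, and with quantile normalization over all arrays that of PYK10 was -1.95. In all, 4129 probe sets were higher and 6021 lower in control shoots among 16049 tested (limma, adjusted p under 0.05), which is 63.2% of those tested; the balance of the 2 numbers depends on the scaling, with 4714 and 5300 after median centring and 4803 and 5514 after quantile normalization over all arrays. The description fields of the shoot samples also mention roots, whereas their titles and sources name shoots, and the levels above follow the titles.

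In roots, the largest named rises with selenate were those of BGLU28, CML38, ORA47, CML37 and STZ. BGLU28 (AT2G44460), a beta-glucosidase gene that marks sulfur deficiency, went from a signal of 31.8 ± 14.6 (SD, n = 2) in control roots to 7594 ± 908 in selenate roots, which is 136-fold on the log2(signal + pseudocount) scale (log2 change 7.09 ± 0.23 SE, limma adjusted p = 1.08e-06). The calmodulin-like genes CML38 and CML37 rose 38.9-fold and 30.9-fold. The transcription factor genes ORA47, of the AP2/ERF family, and STZ, a zinc finger repressor, rose 34.1-fold and 27.3-fold, and STZ reached a signal of 9842 ± 452. The other genes among the 10 largest named rises were GRX480 (a glutaredoxin, 13.5-fold), AR781 (13.1-fold), PUB23 (a U-box ubiquitin ligase, 10.2-fold), EXLA3 (an expansin-like protein, 7.26-fold) and OPCL1 (a ligase of jasmonate synthesis, 7.25-fold). Where control signals lie near the pseudocount, the size of a fold depends on it: with 4 times the pseudocount the log2 changes were 5.87 for BGLU28, 4.04 for CML38, 3.36 for CML37, 4.21 for ORA47 and 1.97 for EXLA3, and with one of 1% of the scaled mean 7.75 for BGLU28, 5.97 for CML38 and 6.31 for CML37.

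The largest named falls in roots were smaller. APS4 (AT5G43780), which encodes an isoform of ATP sulfurylase, the enzyme that activates sulfate, fell from a signal of 4802 ± 197 to 1178 ± 17.7 (SD, n = 2), a 4.01-fold fall (limma adjusted p = 0.000107). OCT1, an organic cation transporter gene, fell 3.92-fold. LHCB4.2, of the light-harvesting antenna, and PORB, of chlorophyll synthesis, fell 3.52-fold and 2.94-fold. ROXY2, bZIP58, LEA4-5, SWEET3, HIS1-3 and BGLU45 fell between 2.39-fold and 2.92-fold. With 4 times the pseudocount the log2 changes were -0.99 for LHCB4.2, -0.81 for PORB and -0.84 for ROXY2, and with one of 1% of the scaled mean -2.40 for LHCB4.2 and -2.16 for PORB. In all, 537 probe sets were higher and 380 lower in selenate roots at an adjusted p under 0.05 (limma), 5.71% of the 16049 tested. At a change of at least 4-fold the numbers were 195 higher and 16 lower. Of the 917 called probe sets, 442 matched 1 gene and 459 were unnamed here.

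**Figure D2:**
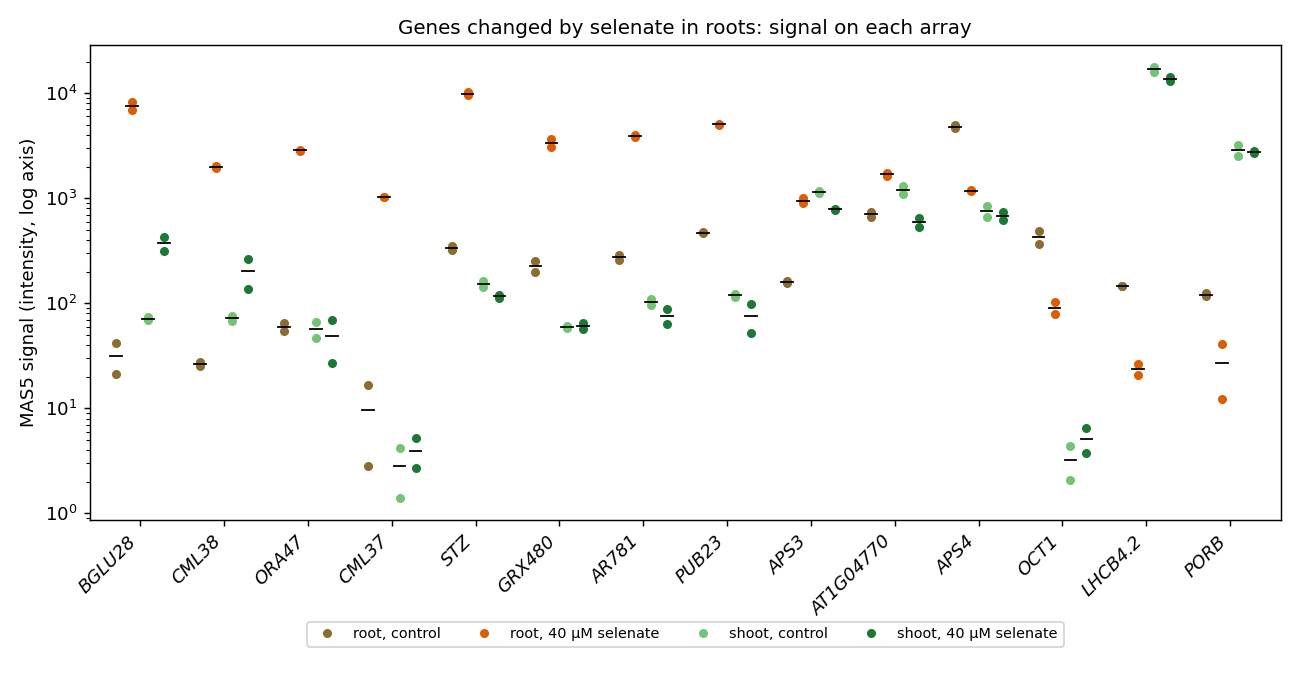
Signal (intensity, log axis) on each of the 8 arrays for 14 genes changed by selenate in roots; points are arrays, coloured by group, and short lines are group means (n = 2). In roots BGLU28 went from 31.8 to 7594 and APS4 from 4802 to 1178, while the shoot signals of STZ were 153 in controls and 117 with selenate.

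Few members of the fixed gene lists could be named. Among the sulfate assimilation genes APS3, another ATP sulfurylase isoform, rose 5.25-fold in roots while APS4 fell, and SIR (sulfite reductase) had a log2 change of 0.32 (limma adjusted p = 0.526). Both tested sulfur-deficiency markers rose, BGLU28 as above and AT1G04770 by 2.36-fold (adjusted p = 0.00218). All 3 tested heat-shock genes rose, AT1G53540 by 5.56-fold (log2 change 1.75 with 4 times the pseudocount), AT2G29500 by 2.79-fold and AT5G51440 by 2.77-fold, and the list was called as a set (limma camera, mean log2 change 1.81, adjusted p = 4.05e-06; adjusted p = 0.0688 with an estimated correlation). In the photosynthesis list 2 of 7 members fell, PSAE-1 by 0.97 and LHCB4.1 by 0.69 on the log2 scale, and adjusted over the list alone PSAN (-0.92) and PRK (-0.52) made it 4. All 7 had negative changes, and the list was lower as a set (limma camera, mean -0.56, adjusted p = 0.00206; adjusted p = 0.110 with an estimated correlation). Both chlorophyll synthesis genes fell, PORB as above and CHLM by 0.86 on the log2 scale.

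Single members of other lists also changed in roots. MGL (methionine gamma-lyase) rose by 0.76 (log2) among 5 genes of methionine and selenium metabolism, and GSTU27 by 1.31 among 8 glutathione genes. BCAT4, of methionine chain elongation in aliphatic glucosinolate synthesis, fell 2.08-fold (limma adjusted p = 0.00465), 1 of 2 tested genes of that list. OPCL1 was the riser among 2 jasmonate genes, GRX480 among 2 salicylate and defence genes, and WRKY53 (7.05-fold; log2 change 2.19 with 4 times the pseudocount) among 2 senescence genes. The root hair expansin gene EXPA7 fell 2.23-fold, and EXPA18 had a log2 change of -1.34 (limma adjusted p = 0.178), while both were counted as lower adjusted over the list alone. The root marker PYK10 had a log2 change of 0.08. No member of the lists for ethylene (1 tested), oxidative stress (3), abscisate, cold and drought (3), auxin (3), phenylpropanoids and anthocyanins (3), iron and zinc (3), indole glucosinolates and camalexin (1) or cell division (1) passed the test over all probe sets in roots. Adjusted over the list alone, UGT74B1 (indole glucosinolates, 0.46), GH3.3 (auxin, -0.80), AT3G13610 (iron and zinc, -0.62) and GSTU28 (glutathione, -0.77) passed. By limma's fry the adjusted p in roots was 1.78e-05 for heat shock, 0.00660 for photosynthesis and 0.00681 for sulfate assimilation, where 1 gene rose and 1 fell. It was 0.0123 for auxin (mean log2 change -0.51), 0.0420 for abscisate, cold and drought (-0.27) and above 0.05 for the other lists tested.

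All 10 named rises in roots kept an adjusted p under 0.05 in limma with each of the 8 arrays left out in turn, and so did the falls of APS4, OCT1 and LHCB4.2. Of the 33 calls in roots named above, 13 ended without root control 1 (adjusted p 0.0557 to 0.418), 11 without root control 2 (0.0572 to 0.217), 10 without root selenate 1 (0.0585 to 0.266) and 11 without root selenate 2 (0.0604 to 0.397). ROXY2, bZIP58, LEA4-5, SWEET3, BGLU45, MGL, LHCB4.1, CHLM and EXPA7 were among them each time, PORB without either control, HIS1-3 without root control 1, BCAT4 without root control 1 or selenate 2, PSAE-1 without root control 1 or selenate 1, and AT5G51440 without root control 2 or selenate 2. LHCB4.1 also lost its call without shoot selenate 1 or shoot selenate 2. AT3G13610, PSAN, GSTU28 and EXPA18 gained one without shoot control 1 or shoot control 2. Limma called 321 higher and 89 lower without root control 1, 318 and 105 without root control 2, 322 and 123 without root selenate 1, and 297 and 101 without root selenate 2. It called 649 lower without shoot control 1 and 646 without shoot control 2, and 997 higher and 1147 lower with only the root arrays in the fit.

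In shoots 299 probe sets were called against 917 in roots, and 2331 in shoots and 2388 in roots had an unadjusted p under 0.05 (limma). Both comparisons used 1 shared spread, although shoot replicates differed more than root replicates. Neither pair of counts therefore shows in which organ more transcripts changed. PUB19, a U-box ubiquitin ligase gene, rose from a signal of 53.0 ± 49.1 (SD, n = 2) in control shoots to 736 ± 146 in selenate shoots, 10.8-fold (log2 change 3.43 ± 0.37 SE, limma adjusted p = 0.00542); the log2 change was 4.13 without shoot control 1, 2.74 without shoot control 2, 2.54 without both shoot arrays with high ratios and 2.48 with 4 times the pseudocount. BGLU28 rose 4.07-fold, from 71.7 ± 3.61 to 372 ± 77.6. UGT73C1, a glycosyltransferase gene, rose 3.72-fold, the cold-regulated gene COR15A 3.60-fold, LEA4-5 by 1.58 (log2) and the senescence-associated gene SAG29 2.85-fold. The other named rises belong to mitochondria: cox2 and cox1, subunits of cytochrome c oxidase, rose 3.58-fold and 2.72-fold, ccb203, of cytochrome c biogenesis, 3.20-fold, and NDB2, an alternative NADH dehydrogenase encoded in the nucleus, 2.67-fold. With 4 times the pseudocount the log2 changes were 0.99 for UGT73C1, 0.84 for ccb203 and 0.85 for LEA4-5, with one of 1% of the scaled mean 2.61 for UGT73C1 and 2.42 for ccb203, neither then called (limma adjusted p = 0.0991 and 0.0706), and without both shoot arrays with high ratios 2.50 for cox2.

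The defensin genes PDF1.2b and PDF1.2 fell 6.58-fold and 3.47-fold in shoots, on probe sets that can cross-hybridise within this gene family in the case of PDF1.2b. The log2 change of PDF1.2 was -1.21 without shoot control 1 (limma adjusted p = 0.0624) and -2.39 without shoot control 2, and -2.57 without both shoot arrays with high ratios. With 4 times the pseudocount the log2 changes of PDF1.2b and ARR15 were -1.92 and -1.14. ARR15, a response regulator of cytokinin signalling, fell 3.32-fold (log2 change -1.73 ± 0.21 SE). BCAT4 fell 2.76-fold from 7427 ± 702 to 2676 ± 243 (log2 change -1.46 ± 0.16 SE, limma adjusted p = 0.00542). GH9B8 (an endoglucanase), GH3.3 (an auxin-conjugating enzyme), ATLP-1, ASPGB1 (an asparaginase), TRM24 and ATL8 fell between 2.25-fold and 2.44-fold. In all, 171 probe sets were higher and 128 lower in selenate shoots at an adjusted p under 0.05 (limma), 1.86% of those tested. Of the 299, 140 matched 1 gene and 42 had a symbol.

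**Figure D3:**
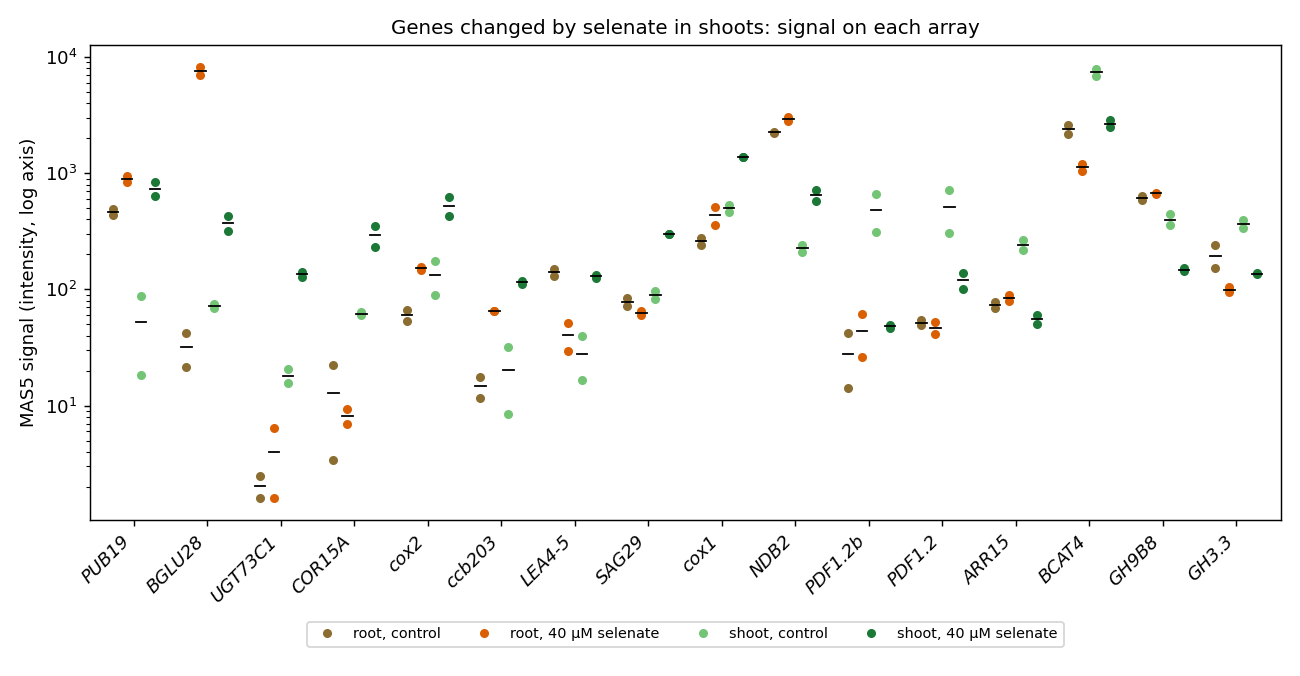
Signal (intensity, log axis) on each of the 8 arrays for 16 genes changed by selenate in shoots; points are arrays, coloured by group, and short lines are group means (n = 2). PUB19 went from 53.0 to 736 in shoots and BCAT4 from 7427 to 2676, while the control shoot signals of PDF1.2b, with a mean of 486 ± 244, lay far apart.

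Of the fixed lists, none was called as a set in shoots by limma camera (0 of the 10 lists tested), and 0 by camera with an estimated correlation. With limma's fry the adjusted p was 0.00923 for abscisate, cold and drought, 0.0223 for auxin, 0.0223 for heat shock and above 0.05 for the other lists. At an unadjusted p under 0.05, camera counted 1 list with the preset correlation and 0 with the estimated one. In the abscisate, cold and drought list, COR15A and COR47 (0.68 log2, limma adjusted p = 0.0475) rose and LTI30 had a log2 change of -0.17, with a list mean of 0.79 (camera adjusted p = 0.0727). The sulfur-deficiency markers parted, BGLU28 rising and AT1G04770 falling 2.00-fold (adjusted p = 0.0230). None of APS3 (-0.53), APS4 (-0.14) and SIR (0.16) passed the test over all probe sets. GSTU16 rose 2.44-fold among the 8 glutathione genes, BCAT4 fell among the aliphatic glucosinolate genes, PDF1.2 among the jasmonate genes and GH3.3 among the auxin genes. The 7 photosynthesis genes had a mean log2 change of -0.08 and the 2 chlorophyll genes one of -0.12, with no member called. No member was called in shoots in the lists for methionine and selenium metabolism (mean 0.21), indole glucosinolates (-0.01), ethylene (0.14), salicylate and defence (0.14), oxidative stress (0.49), heat shock (0.31), phenylpropanoids and anthocyanins (0.02), senescence (-0.02), iron and zinc (-0.15), cell division (-0.53), root hair (0.20) or the root marker PYK10 (-0.26). Adjusted over the list alone, APS3, AT2G29500 and PRL (cell division) passed as lower and AT2G21640 (oxidative stress), AT5G51440 and EXPA7 as higher.

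The shoot calls of PUB19, BGLU28, NDB2, ARR15 and BCAT4 held in limma with each of the 8 arrays left out in turn. Of the 23 calls in shoots named above, the other 18 ended without shoot selenate 1 (adjusted p 0.0578 to 0.209) and 16 of these, all but GH9B8 and ASPGB1, without shoot selenate 2 (0.0563 to 0.159). COR15A, LEA4-5, PDF1.2, GH3.3, TRM24, GSTU16 and COR47 ended without shoot control 1 (0.0513 to 0.0686). Leaving out a root array, which lowers the residual degrees of freedom, ended 10 without root control 1 (0.0517 to 0.131) or root control 2 (0.0516 to 0.130) and 13 without root selenate 1 (0.0536 to 0.119) or root selenate 2 (0.0529 to 0.119). The abscisate, cold and drought list gained a call without root control 1 (camera adjusted p = 0.0496) or root control 2 (0.0476). Limma called 32 higher and 19 lower without shoot selenate 1, 53 and 36 without shoot selenate 2, 359 and 272 without shoot control 2, 75 and 33 without root control 1, 75 and 34 without root control 2, and 69 and 34 without root selenate 1 or root selenate 2. On only the shoot arrays it called 0 and 0 (672 and 648 at an unadjusted p under 0.05), and with the replicate number as a block within organ 0 and 0 (861 and 895). In data simulated with the spread of each organ (16049 probe sets), 20.8% of the calls made in the shoot comparison were false, against 1.55% in the root comparison. With a weight for each organ, 4 of the 10 largest named rises and 5 of the 10 largest named falls in shoots kept their call (limma).

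The responses of roots and shoots were compared directly, as the shoot response minus the root response. Among named genes the largest differences toward roots were those of ORA47, STZ, BGLU28, CML37 and CML38, with log2 values of -5.29 ± 0.40, -5.10 ± 0.22, -5.06 ± 0.32, -4.89 ± 0.39 and -4.12 ± 0.38 (SE; limma adjusted p between 3.12e-05 and 0.000361). Toward shoots the largest among named genes were those of LEA4-5, PUB19, OCT1, COR15A and APS4, with 2.95 ± 0.41, 2.53 ± 0.53, 2.06 ± 0.37, 1.99 ± 0.45 and 1.86 ± 0.24, and the value of PUB19 was 3.23 without shoot control 1 and 1.84 without shoot control 2. With 4 times the pseudocount the values were 1.64 for LEA4-5, 1.67 for PUB19, 1.32 for COR15A, -4.30 for ORA47, -4.42 for BGLU28, -3.35 for CML37 and -3.26 for CML38, and with one of 1% of the scaled mean 3.86 for LEA4-5 and -6.10 for CML37. Without both shoot arrays with high ratios they were 1.65 for PUB19 and -4.69 for ORA47, and with quantile normalization over all arrays -5.73 for BGLU28. LEA4-5 fell in roots and rose in shoots, and AT1G04770 did the opposite, with a difference of -2.24 (limma adjusted p = 0.00103). Among the lists, heat-shock genes differed toward roots (mean -1.49, camera adjusted p = 0.00188), and abscisate, cold and drought genes (1.06, 0.0148) and photosynthesis genes (0.48, 0.0279) toward shoots; each had an adjusted p of 0.177 with an estimated correlation. With limma's fry the adjusted p for the difference was 0.000119 for heat shock, 0.00401 for abscisate, cold and drought, 0.00591 for sulfate assimilation and 0.0222 for photosynthesis. The other lists had an adjusted p above 0.05 by fry. The 3 sulfate assimilation genes did not move together, with 1 called toward shoots, 1 called toward roots and 1 not called. Their mean difference was -0.41 with an SD of 2.40 (camera adjusted p = 0.785). In all, 228 probe sets had a more positive response in shoots and 366 in roots (limma, adjusted p under 0.05).

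The response lists overlapped in part. Among the called probe sets, 29 were higher in both organs, against 5.72 for independent lists (Fisher's exact test, two-sided, p = 4.80e-13), and 17 were lower in both, against 3.03 (p = 9.06e-09, exact). BGLU28 was among the shared rises and BCAT4 among the shared falls. A further 11 were lower in roots and higher in shoots, against 4.05 (exact p = 0.00256), and 7 the reverse, against 4.28 (exact p = 0.207). Across the 16049 probe sets, which are not independent replicates, the log2 changes in roots and shoots had a Pearson correlation of 0.0935. The spread of each probe set was estimated from all 8 arrays for both lists, so the lists are not independent and shared calls are raised in every direction, which the expected numbers do not allow for. Among the 64 probe sets called in both organs, 46 changed in the same direction (Fisher's exact test on the directions, two-sided, added after seeing the data, p = 0.00150). That test treats the probe sets as independent, although they come from the same arrays and can vary together, so its p-value may overstate the evidence. With 1 array left out in turn, limma ended 3 of the 10 named calls for the difference, PUB19, OCT1 and COR15A, without root control 1 (adjusted p 0.133 to 0.198), root selenate 1 (0.0908 to 0.154) or root selenate 2 (0.0581 to 0.189). PUB19 and OCT1 ended without root control 2 (0.0590 to 0.119), PUB19 and COR15A without shoot selenate 1 (0.0582 to 0.112) or shoot selenate 2 (0.0614 to 0.138), and COR15A without shoot control 1 (0.0617). The photosynthesis list lost its call for the difference without root control 1 (camera adjusted p = 0.0989), root selenate 2 (0.0573), shoot control 2 (0.121) or shoot selenate 2 (0.128), and the abscisate, cold and drought list without shoot control 2 (0.121).

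The numbers called for the difference, toward shoots and toward roots, were 45 and 210 without root control 1, 56 and 206 without root control 2, 74 and 202 without root selenate 1, and 50 and 183 without root selenate 2 (limma). Toward shoots they were 384 without shoot control 1, 484 without shoot control 2, 113 without shoot selenate 1 and 144 without shoot selenate 2. The numbers shared, higher and lower, were 11 and 4 without root control 1, 11 and 6 without root control 2, 9 and 5 without root selenate 1, and 11 and 5 without root selenate 2. They were 49 and 33 without shoot control 1, 62 and 38 without shoot control 2, 12 and 4 without shoot selenate 1, and 17 and 10 without shoot selenate 2.

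**Figure D4:**
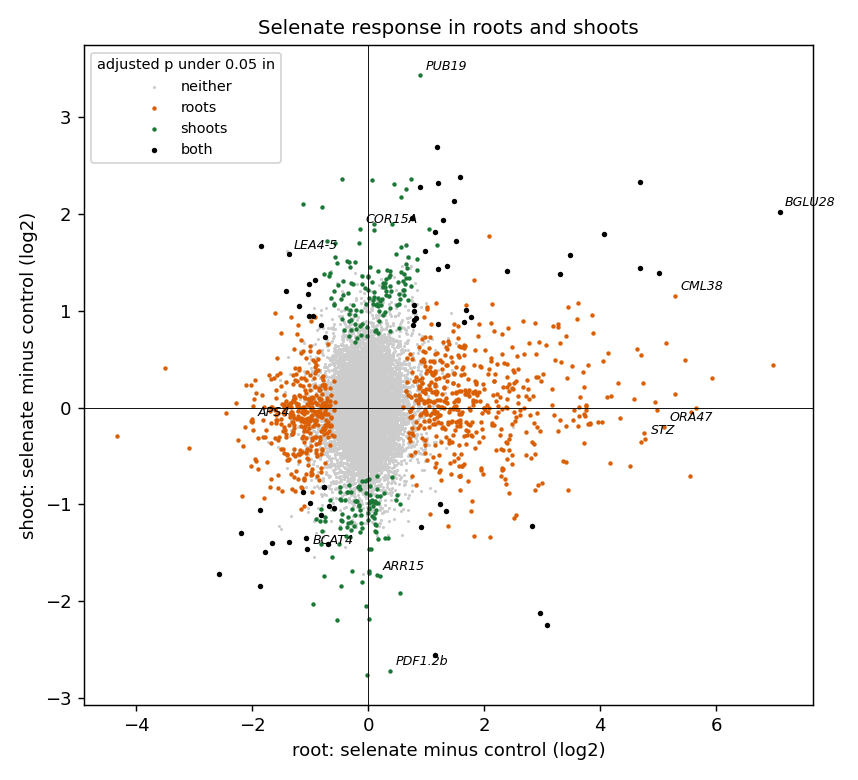
Log2 change by selenate in roots (horizontal) and shoots (vertical) for each of the 16049 probe sets tested, coloured by the organ in which the adjusted p was under 0.05. BGLU28 lies at 7.09 in roots and 2.03 in shoots, and ORA47 and STZ lie at -0.20 and -0.33 in shoots.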

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

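The tests of explanations in this part were chosen only after the results were seen, while the test of the difference between organs was fixed beforehand. The test of carry-over below replaced earlier forms, on the 4 called genes together and then on how far abundant shoot genes fell in roots, after their outcomes and the levels it uses were seen, and the genes were parted by the share they need. By the test of the difference between organs, 228 probe sets had a more positive response in shoots and 366 a more positive response in roots (limma, adjusted p under 0.05). Among the named genes, the shoot response minus the root response was 2.95 (log2) for LEA4-5, 2.53 for PUB19, 2.06 for OCT1, 1.99 for COR15A, 1.86 for APS4, -5.29 for ORA47, -5.10 for STZ, -5.06 for BGLU28, -4.89 for CML37 and -4.12 for CML38. As list means it was -1.49 for heat-shock genes, 1.06 for abscisate, cold and drought genes and 0.48 for photosynthesis genes, each with an adjusted p of 0.177 with an estimated correlation. The 25S ribosomal RNA control probe set, which no comparison used, had signals of 596 on shoot selenate 1 and 6262 on shoot selenate 2, above the control shoots at 154 and 218.

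Of 9 photosynthesis and chlorophyll genes 4 were called lower in selenate roots, and the photosynthesis list was lower as a set (camera adjusted p = 0.00206; adjusted p = 0.110 with an estimated correlation), a sign that more green tissue carried over into the control root samples would also give. PORB, CHLM and LHCB4.1 need shoot tissue worth at least 1.59% of the shoot signal, which would leave no abundant shoot transcript below that level in control roots. Of 225 other probe sets with a signal of at least 10000 in control shoots, however, 22 lay below it and 10 below 0.5 of it, down to 0.213%. This argues against carry-over as the whole cause for these 3. The argument is weakened because those 10 had control root signals of only 33.05 to 175.7, where MAS5 values carry large relative errors. The argument also assumes that any carried-over tissue had the transcript mix of the control shoot samples, which was not tested. PSAE-1 needs 0.582% and LHCB4.2 0.728%, and of the 225 only 4 lay below the first and 7 below the second, 1 of them below 0.5 of either. Of 20 abundant shoot-specific probe sets, LHCB4.2 among them, 19 fell in selenate roots, by a median of 0.360% of the shoot signal and at most 0.820%, but 5, CaS and HPR among them, changed by less than 0.25 of what PSAE-1 needs, so these values go both ways, and carry-over and a change within roots cannot be told apart for these 2 genes. RNA integrity is argued against by the GAPDH ratio, whose mean log2 value in selenate roots differed from that in control roots by -0.0262, and a lower level of these nuclear transcripts in selenate roots remains open and untested.

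The shoot arrays deviated crosswise from their group means, control 1 with selenate 2 and control 2 with selenate 1. RNA integrity is a candidate explanation: the actin 3'/5' ratio, which was not used to find the pattern, was 55.9 and 51.7 on control 2 and selenate 1 against 21.2 and 22.9 on control 1 and selenate 2, a gap of 2.26-fold between the nearest arrays. An earlier form of this test also used the number of calls with the GAPDH ratio as a covariate, which rises by construction, and that part was dropped after its outcome was seen. The ubiquitin ratio did not part the arrays this way, at 4.38 and 4.88 on the controls and 5.24 and 6.11 on the selenate arrays, and no biological explanation was tested.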

How the results depend on the processing

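No called gene named in the text and no called fixed list reversed its direction under any setting run, and the organ weights, the integrity covariate, the crossed pairing and the removal of shoot arrays with high 3'/5' ratios were chosen after seeing the data. Counts below are limma calls, higher then lower. The replicate numbers share no stated origin: deviations of same-numbered arrays correlated at 0.339 in roots and -0.485 in shoots. In roots the actin ratio was 9.07 (control) and 8.17 (selenate) on arrays numbered 1, against 5.42 and 4.74 on those numbered 2. The main fit did not pair arrays by number. The replicate block within organ, with 2 residual degrees of freedom left, gave 324 and 113 in roots, 0 and 0 in shoots (861 and 895 at an unadjusted p under 0.05), 19 and 130 for the difference and 0 and 0 shared, and the block across organs 83 and 40 in shoots, 124 higher for the difference and 16 and 9 shared. The crossed pairing of the shoot numbers gave 876 and 1004 in roots, 799 and 782 in shoots, 980 and 931 for the difference and 127 and 121 shared. The integrity covariate gave 908 and 1052, 850 and 804, 1003 and 924, and 141 and 126. Without the shoot arrays with high ratios there were 958 and 1088, 377 and 368, 645 and 713, and 89 and 80, and 1 list called for the difference. Organ weights gave 1017 and 1167 in roots and 59 and 28 in shoots. With them, 4 of the 10 largest named rises and 5 of the 10 largest named falls in shoots kept their call. In roots all 10 of each did. In the simulation with the spread of each organ (16049 probe sets) false calls with these weights made up 13.4% in roots and 6.11% in shoots, against 1.55% and 20.8% without. Only the root arrays gave 997 and 1147, and only the shoot arrays 0 and 0 (672 and 648 at an unadjusted p under 0.05). With no filter 83 were lower in shoots, and at a 2-fold minimum 234 were lower in roots, 83 in shoots, 4000 in control shoots against control roots, and 18 and 9 were shared. Lists called in shoots numbered 1 with 4 times the pseudocount, 1 on only the shoot arrays and 0 or 1 with 1 array left out. With an estimated correlation, camera called 0 lists in roots and 0 for the difference. With each array left out in turn, the counts were 297 to 701 and 89 to 649 in roots, 32 to 359 and 19 to 272 in shoots, 45 to 484 and 183 to 533 for the difference, 9 to 62 and 4 to 38 shared, and 1 to 3 lists for the difference; the lone array left was assumed to vary like the other groups. Fewer arrays and residual degrees of freedom did not lower such counts in every case. Only the root arrays gave more root calls than the 537 and 380 of the main fit. In shoots the counts reached 359 and 272 with 1 array left out, against 171 and 128 in the main fit. Leaving out arrays also changes the spread shared by roots and shoots, whose replicates differed unequally. A covariate or pairing that follows the crosswise deviation of the shoot arrays raises the counts by construction. The cause of the other shifts, those with fewer arrays among them, was not tested. Of the single genes and lists under all alternatives, 2227 gene values and 946 list values kept their side of the threshold, 372 and 14 lost the call and 52 and 4 gained it. Scaling over all arrays by quantiles or by medians each shifted the median of control shoots minus control roots by 0.13 (log2). Changes among signals below the pseudocount are not resolved on this scale.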

Other observations

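All tests in this part were chosen only after the data were seen, and those of RNA integrity and of unpolyadenylated RNA were rewritten after earlier forms had been run. The 14 tested mitochondrially encoded transcripts all had positive changes in selenate shoots, with a median log2 change of 1.31, and limma called 6 of them, cox2 (1.84), ccb203 (1.68), cox1 (1.44), nad9 (1.40), ccb452 (1.38) and ccb206 (0.92). In roots 13 of the 14 were positive, and matR (2.08; 3.25 with a pseudocount of 1% of the scaled mean and 0.97 with 4 times the pseudocount) and ccb206 (0.83) were called. As a set they passed limma's camera over 40 added lists in shoots (adjusted p = 2.63e-12) and in roots (2.34e-07), but not with an estimated correlation (adjusted p = 0.484 in shoots and 0.318 in roots). The responses of the set in the 2 organs differed by a mean of 0.32, which was not called (camera adjusted p = 0.213). The 69 plastid-encoded genes had a median log2 change of 0.0812 in shoots (camera adjusted p = 0.0790) and of 0.20 in roots, where 49 were positive (mean 0.18, camera adjusted p = 0.0302; adjusted p = 0.938 with an estimated correlation).

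For the mitochondrial pattern in shoots, the 25S signal was 154 and 218 on the control shoots and 596 and 6262 on the selenate shoots, and the 5S signal 159 and 340 against 558 and 420; the 25S signal was 3.39 (log2) higher on shoot selenate 2 than on shoot selenate 1 while the mitochondrial median differed by -0.0751, so carry-over of ribosomal and other unpolyadenylated RNA and an effect of selenate cannot be told apart. Lower RNA integrity as read by the GAPDH ratio is argued against, since the mean log2 ratio of the selenate shoots differed from that of the control shoots by 0.0205; as a covariate it left the mitochondrial median at 1.31 with 11 of the 14 called, although this balance fixes the median in advance. The ubiquitin ratio was higher on both selenate shoots than on both controls, by 1.07-fold between the nearest arrays, so lower RNA integrity as read by it and an effect of selenate cannot be told apart. A higher yield of all organelle transcripts would raise plastid genes alike, and their median of 0.0812 lies below the mitochondrial one by more than the SD of the mitochondrial changes, 0.61, which argues against it. Longer poly(A) tails on these transcripts and binding by nuclear copies of mitochondrial sequence were not tested.

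Families of gene symbols were counted in the same way. In roots CML38, CML37 and CML23 (2.38) rose among 6 calmodulin-like genes, and PUB23, PUB22 (2.17) and PUB24 (1.07) among 8 U-box genes, with camera adjusted p of 1.78e-05 and 2.19e-05 over the 40 lists and of 0.107 for both families with an estimated correlation. WRKY53 and WRKY22 (1.91) rose among 5 WRKY genes (camera adjusted p = 0.00908; adjusted p = 0.504 with an estimated correlation). In shoots UGT73C1, UGT84A3 (1.31) and UGT73B5 (1.12) rose among 34 glycosyltransferase genes (camera adjusted p = 0.0155; adjusted p = 0.484 with an estimated correlation). Of 10 genes with GH symbols, which join endoglucanase and auxin-conjugating genes, GH9B8, GH9B13 (-1.05), GH9C1 (-1.05; -2.06 with a pseudocount of 1% of the scaled mean and -0.39, not called, with 4 times the pseudocount) and GH3.3 fell in shoots (camera adjusted p = 0.0327; adjusted p = 0.617 with an estimated correlation). Of the 6 root calls added in this part, matR, ccb206 and PUB24 ended in limma without root control 1 (adjusted p 0.105 to 0.214), root control 2 (0.0796 to 0.219), root selenate 1 (0.102 to 0.244) or root selenate 2 (0.0902 to 0.161). Of the 7 shoot calls added, all ended without shoot selenate 1 (0.0748 to 0.195), all but nad9 without shoot selenate 2 (0.0503 to 0.150), ccb206 without shoot control 1 (0.0763), and ccb206, UGT84A3, UGT73B5 and GH9C1 without shoot control 2 (0.0503 to 0.0644). All but nad9 and ccb452 ended without root control 1 (0.0573 to 0.127), root control 2 (0.0567 to 0.126), root selenate 1 (0.0615 to 0.120) or root selenate 2 (0.0606 to 0.119).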
